A study of Rattus norvegicus with 19 samples.

How the data were processed

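Gene expression was measured in adult rat liver on 2 Affymetrix array types, 10 arrays of the first (5 PCN, 5 corn oil) and 9 of the second (5 PCN, 4 corn oil). Per the labels, total RNA was extracted with RNeasy columns and DNase digestion on the column, and biotinylated cRNA was made by the Affymetrix protocol. The values were deposited by the authors as log2 expression per probe set, already processed before deposit. The submitters' processing notes name MAS5 with no version, and the sources used here do not describe the summarization, background correction or normalization behind these values. MAS5 signals are linear, whereas the deposited values ran from 4.31 to 15.2 on the first array type and from 3.10 to 14.1 on the second. The base was inferred to be 2 because the highest value exceeds the natural logarithm of the largest 16-bit scanner reading (11.1) and lies below its binary logarithm. The 2 tables are on different scales and were tested separately.

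The plan fixed before the data were examined assumed linear MAS5 signals, to be scaled to a trimmed mean and transformed with a pseudocount of 16. Since the values were already log2, they were analysed as deposited, and the planned transformation was run as an alternative. The plan also fixed the test, the 31 gene lists and the rule for naming genes.

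The first array type held 15923 probe sets, of which 12789 mapped to a single gene, 312 to several and 2822 to none. The second held 15333, with 7570, 100 and 7663 in these classes. Current gene symbols came from the RefSeq annotation of the rat assembly GRCr8, matched by gene identifier. Probe sets with several genes or none were tested and counted but not named. Among called probe sets 55 on the first array type and 217 on the second had no single gene. The 57 control probe sets of each array type were left out, as were probe sets with a mean below the 30th percentile (6.67 and 5.51), which left 11106 and 10693. Arrays have no sequencing depth, so precision is limited by their number.

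Each probe set was compared between PCN and corn oil with limma 3.58.1 in R 4.3.3, as a linear model with treatment alone and moderated variances with an intensity trend. Tests were two-sided, with Benjamini-Hochberg adjustment within an array type and a threshold of 0.05 on the adjusted p. At an unadjusted p below 0.05 there were 1964 and 2919 probe sets. Fold changes are PCN over corn oil, with the moderated standard error.

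The gene lists covered phase I drug metabolism, phase II conjugation, hepatic transporters, heme synthesis and breakdown, bile acid synthesis, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation and ketogenesis, gluconeogenesis and glucose handling, oxidative stress, heat shock and chaperones, endoplasmic reticulum stress, acute phase proteins, glucocorticoid response, thyroid hormone, the growth hormone axis, nuclear receptors and cofactors, the circadian clock, the cell cycle, apoptosis and p53 response, interferon response, inflammatory mediators, and urea cycle and amino acid breakdown. Marker lists covered hepatocytes, Kupffer cells and macrophages, stellate cells and fibroblasts, endothelial cells, cholangiocytes, red cells, lymphocytes and neutrophils. Each gene was represented by its brightest probe set, taken from the first array type where measured there. Lists with at least 5 genes on the first array type were tested with camera at a preset correlation of 0.01, adjusted over 30 lists. A camera test with an estimated correlation and fry, which asks whether the genes of a list move on balance in a single direction, were run beside it. The mixed form of fry, which counts changes in either direction, was run as well. Per-array list means were compared by an exact permutation test over 252 regroupings.

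Genes were named by a rule with 4 parts. The 14 largest rises and 14 largest falls on the first array type, and 6 and 6 on the second, were taken among single-gene probe sets past the threshold whose groups did not overlap. Each list gave up to 4 called members with the largest change, or its 2 members with the smallest p where none was called. A fixed set of pregnane X receptor and bile acid genes was always named where measured.

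Alternatives planned in advance were pseudocounts of 1 and 64, no filter, a filter at the 50th percentile, scaling to a common median, quantile normalization, the replicate number as a block, variances without a trend or with robust estimation, array weights, an unmoderated test, all probe sets of a gene in the set test, and leaving out each animal in turn. The transformation first planned was meant for the main result, and became an alternative once the values proved to be log2. Chosen after seeing the data were the values as deposited for the main result, and the 2 steps of that transformation run separately. So were cyclic loess, centring on the 100 probe sets common to both array types, and a term for 2 sets of arrays of the first type. Those sets were found by regrouping, with corn oil replicate 2 left out. List counts without corn oil replicate 2 of the first array type and PCN replicate 5 of the second were also chosen then. The trimmed mean left out 2% of the values at each end.

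The pipeline was tested on simulated data with the mean and variance of each probe set, independent normal noise and known changes added, so the simulation holds no correlation between genes. On the first array type it recovered 55.8%, 94.3% and 99.7% of log2 changes of 0.5, 1 and 2, with 4.37% false calls. On the second it recovered 76.7%, 98.5% and 99.7%, with 5.18% false calls. The set test called a list shifted by 0.3 in 5 of 5 draws, and gave 0 calls in 145 tests of the other lists, summed over the draws. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.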

Results

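Adult rat livers were profiled on Affymetrix expression arrays after a single intraperitoneal dose of pregnenolone-16α-carbonitrile (PCN), a synthetic steroid that activates the rodent pregnane X receptor, or of its corn oil vehicle. The PCN dose was 100 mg/kg, given after an overnight fast, and livers were taken 8 h later. The labels describe 5 biological replicates per group, each hybridized to 2 array types. The first array type had 10 arrays, 5 of PCN and 5 of corn oil. The second had 9 arrays, 5 of PCN and 4 of corn oil, because corn oil replicate 2 had none among the deposited values. Values are on the log2 scale, and the number of arrays per group limits the precision of every comparison. The study asked whether PCN activates genes apart from those of drug metabolism, as a way of counteracting stress.

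On the first array type the largest rise was that of Gadd45b, a stress-inducible growth arrest gene, from 7.76 ± 0.60 (SD, n = 5) in corn oil to 10.68 ± 0.47 (SD, n = 5) after PCN. This was a 7.57-fold increase (log2 fold change 2.92 ± 0.29 SE, adjusted p = 0.000375, limma). Cyp26a1, which breaks down retinoic acid, rose 5.46-fold (2.45 ± 0.24, adjusted p = 0.000379), and Mdm2, a ubiquitin ligase that acts on p53, rose 4.90-fold (2.29 ± 0.20, adjusted p = 0.000222). Alas1, the rate-limiting enzyme of heme synthesis, went from 11.68 ± 0.31 to 13.42 ± 0.18 (SD, n = 5 each), a 3.33-fold rise with an adjusted p of 0.000119. Inmt, a methyltransferase of indolamines, rose 4.88-fold, Gpd1l1 3.98-fold, the desmosomal cadherin Dsc2 3.46-fold, the carboxylesterase Ces2c 3.25-fold and Hspa1a, an inducible chaperone, 3.18-fold. Dip2a rose 2.93-fold with the smallest adjusted p of the named genes (1.35e-05), and Cyp2c22 rose 2.80-fold (adjusted p = 0.00803). The rule for the largest rises also took Zfand2a (3.51-fold, adjusted p = 0.0311), C8h11orf54 (2.84-fold, adjusted p = 0.0335) and Gsr, glutathione reductase (2.60-fold, adjusted p = 0.0287). Their calls were lost when certain single arrays were left out, with adjusted p values reaching 0.0834 and 0.0929 without corn oil replicate 4 for Zfand2a and C8h11orf54 and 0.0766 without PCN replicate 4 for Gsr. The call of Zfand2a was lost without any of 7 single arrays, and also with robust variances and in an unmoderated test. Gsr read 7.33 in corn oil replicate 2 and 8.75 to 9.06 in the other corn oil arrays, which enlarged its rise. Without that array and with a term for 2 sets of arrays, described below, its log2 fold change was 1.04 (adjusted p = 0.0189, limma).

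**Figure D1:**
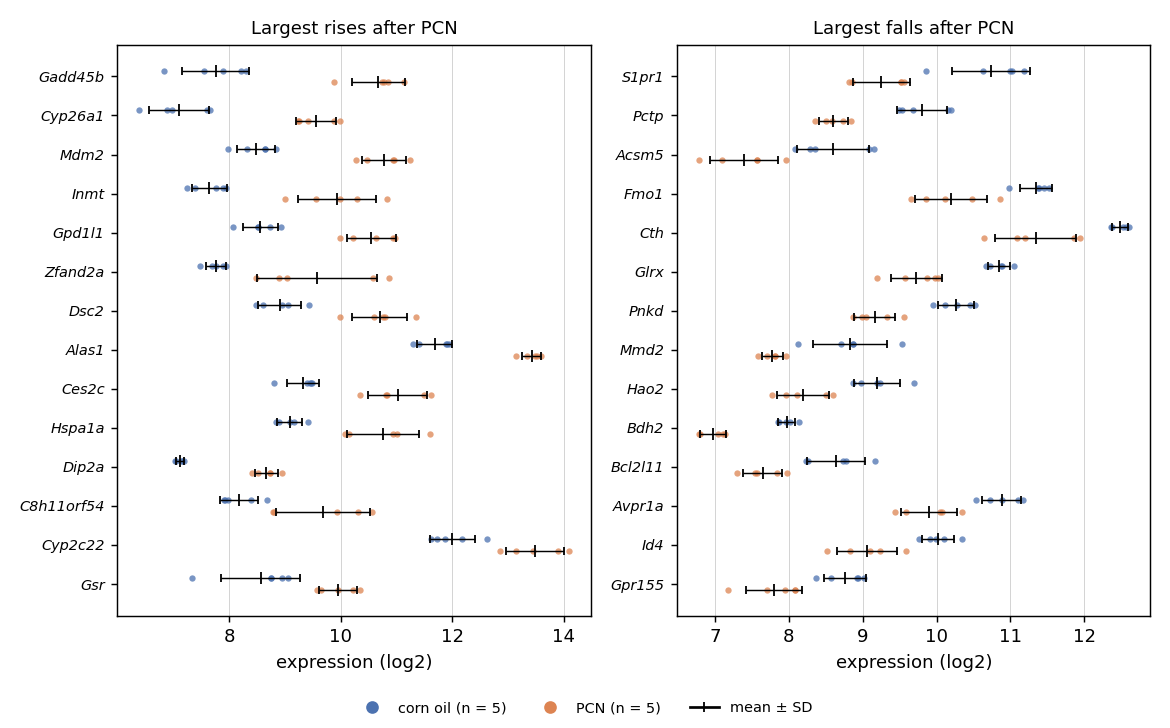
Expression (log2) in each of the 5 corn oil and 5 PCN arrays of the first array type for the 14 largest rises and the 14 largest falls, with points for single arrays and bars for the mean ± SD. Every PCN value lies above every corn oil value for the rises and below for the falls, as the rule for these genes required, and Gadd45b shows the widest separation of means, 7.76 against 10.68.

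S1pr1, a receptor for sphingosine phosphate, was 2.79-fold lower after PCN (log2 fold change -1.48 ± 0.25 SE, adjusted p = 0.00895, n = 5 per group, limma), and Pctp, the phosphatidylcholine transfer protein, was 2.30-fold lower (adjusted p = 0.00231). The flavin monooxygenase Fmo1 was 2.22-fold lower (adjusted p = 0.0119), Cth, an enzyme of cysteine synthesis from methionine, 2.21-fold lower (adjusted p = 0.0147), and the glutaredoxin Glrx 2.16-fold lower (adjusted p = 0.00295). Bdh2 fell from 7.97 ± 0.12 to 6.98 ± 0.17 (SD, n = 5 each), with an adjusted p of 0.000303. Pnkd was 2.15-fold lower by the probe set the rule selected, while its other tested probe set gave a log2 fold change of -0.09. Mmd2, the hydroxyacid oxidase Hao2, the pro-apoptotic gene Bcl2l11, the vasopressin receptor Avpr1a, Id4 and Gpr155 had log2 fold changes between -1.04 and -0.96, with adjusted p values from 0.0143 to 0.0166. Acsm5 had a log2 fold change of -1.20 (adjusted p = 0.0266), and its call was lost without any of 4 single arrays (adjusted p up to 0.0736, without PCN replicate 4). With the term for 2 sets of arrays described in the next paragraph, the calls of Acsm5, Fmo1, Cth, Mmd2, Hao2, Bcl2l11 and Id4 were lost (adjusted p from 0.0527 to 0.0802). In an unmoderated test those of S1pr1, Avpr1a and Gpr155 were lost as well (0.0701, 0.0769 and 0.0787). With the term the log2 fold changes were -1.16 for Acsm5, -1.13 for Fmo1 and -0.99 for Mmd2. They were -0.91 for Cth, -0.84 for Id4, -0.78 for Hao2 and -0.69 for Bcl2l11.

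In all, 256 probe sets were higher and 105 lower after PCN among the 11106 tested on the first array type, so that 70.9% of the 361 called went up. These belonged to 203 named genes that rose and 85 that fell, and 58 probe sets rose and 15 fell by at least 2-fold. The groups did not overlap for 671 probe sets (6.04%), against 0.794% by chance. The share that rose depended on the scaling, at 57.9% after quantile normalization, 59.4% after scaling to a trimmed mean, 59.5% when this was joined to a pseudocount of 16 and 58.9% after centring on the probe sets common to both array types. Counts also depended on single arrays. Numbers of higher and lower probe sets dropped to 142 and 62 without corn oil replicate 3, 107 and 47 without corn oil replicate 4, 137 and 69 without corn oil replicate 5, 134 and 43 without PCN replicate 1, 122 and 65 without PCN replicate 3, and 126 and 52 without PCN replicate 4. When corn oil replicate 2 was left out, a regrouping that set corn oil replicate 1 and PCN replicates 1, 3, 4 and 5 against the other 4 arrays called 973 probe sets, more than the 393 of the treatment. With a term for these 2 sets of arrays beside the treatment, 149 probe sets were higher and 161 lower after PCN (48.1% higher), 179 of the 361 calls were kept and all 361 had the same sign. Beside the 7 genes above, the named calls lost with this term were those of Zfand2a, C8h11orf54, Abcg8, Crot, Gys2, Slc37a4, Srxn1, Chordc1, P4hb, Il1r1, Rxrg, Ccnd1, Oas1a and Cdo1 (adjusted p from 0.0637 to 0.218). Some kept a log2 fold change near the one given for them below, such as Slc37a4 (-0.41) and Cdo1 (-0.53) with the term. Others had a smaller one, such as Crot (-0.97) and Il1r1 (0.59).

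On the second array type Gpd1l1 and Mdm2 had the largest rises that the naming rule took, at 4.20-fold (log2 fold change 2.07 ± 0.19 SE, adjusted p = 0.000692) and 3.53-fold (1.82 ± 0.20, adjusted p = 0.00119), with 4 corn oil and 5 PCN arrays. Rdh10, a retinol dehydrogenase, rose 2.60-fold (adjusted p = 0.00119), the chromatin remodelling gene Smarca2 2.59-fold (adjusted p = 0.00352), and the amino acid transporter Slc43a1 2.43-fold (adjusted p = 0.0082). Ggct, a glutathione cycle enzyme, rose 2.28-fold (adjusted p = 0.0244). The tight junction gene Cldn1 was 2.77-fold lower (log2 fold change -1.47 ± 0.17 SE, adjusted p = 0.0014), and Bbox1, the last enzyme of carnitine synthesis, was 1.85-fold lower (adjusted p = 0.00638). Smoc1, Arhgef3, Stmp1 and Id4 were 1.63-fold, 1.63-fold, 1.60-fold and 1.59-fold lower, with adjusted p values of 0.00593, 0.019, 0.0267 and 0.0463. Without corn oil replicate 4 the adjusted p became 0.0846 for Ggct, 0.063 for Arhgef3, 0.075 for Stmp1 and 0.11 for Id4.

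Among 10693 probe sets tested there, 402 were higher and 175 lower after PCN (69.7% higher), from 271 named genes that rose and 63 that fell. Ubfd1 was called in both directions by different probe sets. The groups did not overlap for 1110 probe sets (10.4%, against 1.59% by chance). Bright probe sets were shifted on these arrays: among 10 groups by brightness, the brightest had a median log2 fold change of 0.20 and the dimmest -0.06. The mean of the 100 probe sets common to both array types was 0.28 higher after PCN (exact permutation p = 0.0238) and 0.11 higher in the same 9 animals on the first array type (exact permutation p = 0.103), both two-sided. The share that rose was 87.8% after scaling to a common median and 44.5% after scaling to a trimmed mean. With the transformation first planned, a trimmed mean joined to a pseudocount of 16, it was 44.0% (394 higher and 501 lower). It was 4.29% after centring on the common probe sets, which moved the median of all probe sets to -0.28. Leaving out corn oil replicate 4 left 69 higher and 15 lower, and leaving out PCN replicate 5 gave 905 and 572. Without corn oil replicates 1 or 3 the counts were 140 and 54 or 213 and 62, and without PCN replicates 1, 2, 3 or 4 they were 135 and 41, 174 and 59, 160 and 46, or 184 and 46.

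**Figure D2:**
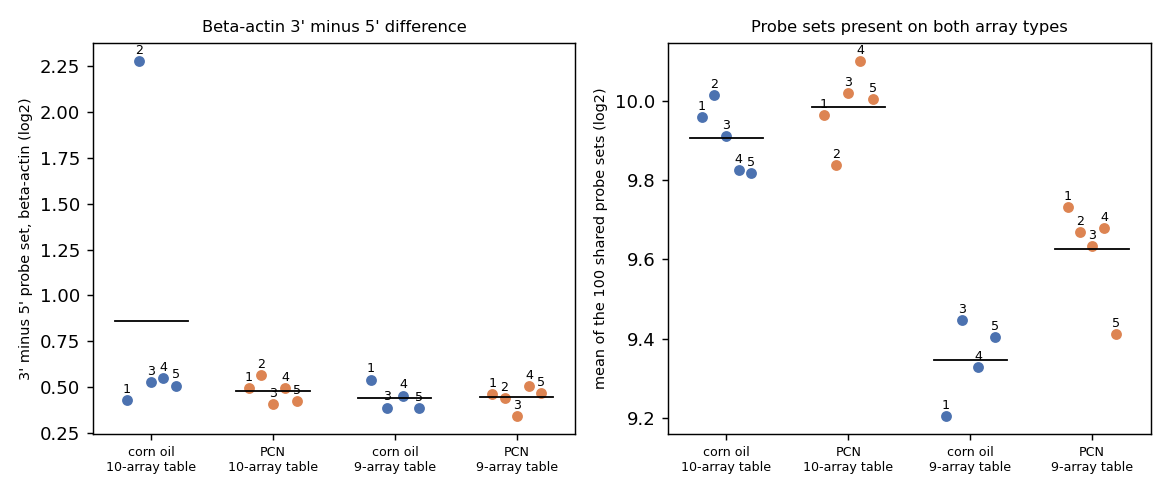
Left, the log2 difference between the 3′ and 5′ probe sets of beta-actin on each array; right, the mean log2 value of the 100 probe sets common to both array types, with points numbered by replicate and lines at group means. Corn oil replicate 2 stands at 2.28 on the left, where the other arrays of its type lie between 0.407 and 0.564, and on the right the PCN arrays of the second type average 0.28 above the corn oil arrays.

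The 2 array types could be compared over 1643 genes measured on both. Across these genes, which are not independent replicates and come from shared animals, the log2 fold changes correlated with Pearson's r = 0.623 and Spearman's rho = 0.504. When the 9 shared animals were regrouped at random, with the same split on both array types, r was 0.620 for the real split and had a median of 0.433 and a maximum of 0.619 in the others (100 of 126 possible splits). Both array types called 31 genes, all in the same direction, against 4.98 if the calls were independent, which shared animals make doubtful. The regroupings give no reference for this count, since none of the others called any of the 1643 genes on the second array type. Among the 31 genes called on both were Mdm2, Gpd1l1, Rdh10, Smarca2, Insig2 and Sc5d, which rose, and Cldn1, Smoc1, Stmp1 and Id4, which fell. Of the 61 shared genes called on the first array type, 54 had the same sign on the second.

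Of 45 measured phase I genes 5 rose and 1 fell, and 8 rose and 2 fell when adjusted over the list alone. Cyp3a23-3a1, a main target of the pregnane X receptor, rose 1.57-fold from an already high level, 13.15 ± 0.25 in corn oil against 13.79 ± 0.04 after PCN (SD, n = 5 each, adjusted p = 0.00543). Cyp3a18 rose 2.49-fold (adjusted p = 0.00384), and Por, the electron donor of the P450 enzymes, 2.42-fold (adjusted p = 0.000751). Cyp3a2 had a log2 fold change of 1.56 ± 0.42 (SE) that missed the threshold (adjusted p = 0.0663), and Cyp3a9 one of 0.17 ± 0.20 (adjusted p = 0.696). The set test did not call the list (adjusted p = 0.165). Among 40 phase II conjugation genes 4 rose and 2 fell (6 and 5 adjusted over the list alone; set test adjusted p = 0.831). Ugt2b1 rose 1.65-fold (adjusted p = 0.00329) and Gstm3 2.10-fold (adjusted p = 0.0274), while Mgst3 and Sult1a1 had log2 fold changes of -0.74 and -0.73 (adjusted p = 0.0291 and 0.046). The last 3 of these calls were lost when single arrays were left out, with adjusted p values up to 0.0703 without PCN replicate 1, 0.0675 without PCN replicate 3 and 0.111 without corn oil replicate 4. Without corn oil replicate 2 of the first array type and PCN replicate 5 of the second, 5 phase I genes rose and 1 fell, and 4 phase II genes rose and 1 fell.

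Of 25 hepatic transporters 5 rose and limma called 0 lower (3 were lower at an unadjusted p below 0.05), and 8 rose and 1 fell when adjusted over the list alone. Abcg5 and Abcg8, which together export sterols, rose 2.28-fold and 2.04-fold (adjusted p = 0.00485 and 0.0279), the drug efflux pump Abcb1a rose 2.04-fold (adjusted p = 0.00543) and the organic anion carrier Slco1a4 rose 1.79-fold (adjusted p = 0.0182). The calls of Abcg8 and Slco1a4 were lost without single arrays (adjusted p up to 0.0797 without corn oil replicate 4 and 0.0535 without PCN replicate 1). The set test gave an adjusted p of 0.0489 for the transporters and an adjusted p of 0.47 with an estimated correlation, and without corn oil replicate 2 it gave 0.132. In heme metabolism 2 of 17 genes rose, Alas1 and the biliverdin reductase Blvrb (1.70-fold, adjusted p = 0.0147, 0.0564 without corn oil replicate 4), and 4 rose and 2 fell adjusted over the list alone. Its set test adjusted p was 0.614, with a mean above 0 and a median below. The receptors themselves did not pass the test, with log2 fold changes of 0.11 ± 0.20 (SE) for Nr1i2 (adjusted p = 0.815) and 0.33 ± 0.25 for Nr1i3 (adjusted p = 0.546). Cyp2b1, Cyp2b2, Abcb1b, Gsta2 and Ugt1a1 had no probe set assigned to a single gene and were not analysed here.

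**Figure D3:**
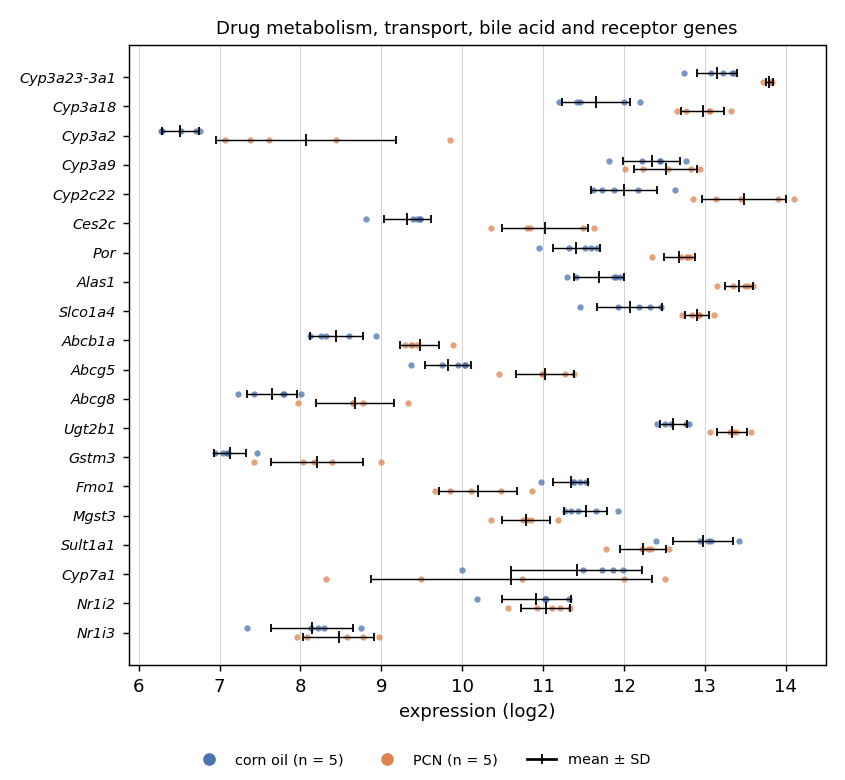
Expression (log2) of drug metabolism, transport, bile acid and receptor genes on each of the 5 corn oil and 5 PCN arrays of the first array type, with points for single arrays and bars for the mean ± SD. Cyp3a23-3a1 moves from 13.15 to 13.79 with little spread after PCN, and the Cyp7a1 values spread most widely after PCN (SD 1.74).

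To address the study's question, the called genes were counted inside and outside the 4 lists of drug metabolism, conjugation, transport and heme. Of 446 genes that rose on either array type 16 were in these lists and 430 were in none, a share of 3.59% (95% exact binomial interval 2.06 to 5.76). Of 144 genes that fell, 4 were in them and 140 were not. A gene counted here if any of its probe sets was called, whereas the list counts above use its brightest probe set. The lists held 127 of the 11118 genes tested, or 1.14%. The intervals given here treat genes as independent, which genes measured in the same animals are not. Over both directions the share was 3.40% (20 of 589 genes, interval 2.09 to 5.20). It was 5.21% without corn oil replicate 3, 8.92% without corn oil replicate 4, 5.19% without corn oil replicate 5, 6.17% without PCN replicate 1, 5.93% without PCN replicate 3, 6.49% without PCN replicate 4 and 1.89% without PCN replicate 5. Centring on the common probe sets brought it to 1.05%, below the share among tested genes, and it was 1.85% with array weights, 6.21% with replicate number as a block and 8.65% in an unmoderated test.

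Heat shock and chaperone genes gave the largest group of calls. Of 25 measured 9 rose and limma called 0 lower (0 also at an unadjusted p below 0.05), 17 rose adjusted over the list alone, and 24 had a positive log2 fold change. Beside Hspa1a, the co-chaperone Bag3 rose 2.13-fold (adjusted p = 0.00393), the small heat shock protein Hspb8 1.70-fold (adjusted p = 0.00708) and Chordc1 1.58-fold (adjusted p = 0.0182, but 0.0561 without corn oil replicate 4). The median log2 fold change of the list was 0.40 and its mean 0.49. The set test gave an adjusted p of 6.3e-14, and the adjusted p was 0.47 with an estimated correlation. The per-array mean of the list was higher in all 5 PCN animals than in every corn oil animal (exact two-sided permutation p = 0.00794, the smallest 252 regroupings can give; 0.0595 after adjustment over 30 lists). The same separation and p were found for hepatic transporters and for apoptosis and p53 response, both higher, and for gluconeogenesis, lower. Without corn oil replicate 2, 7 of these genes rose.

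**Figure D4:**
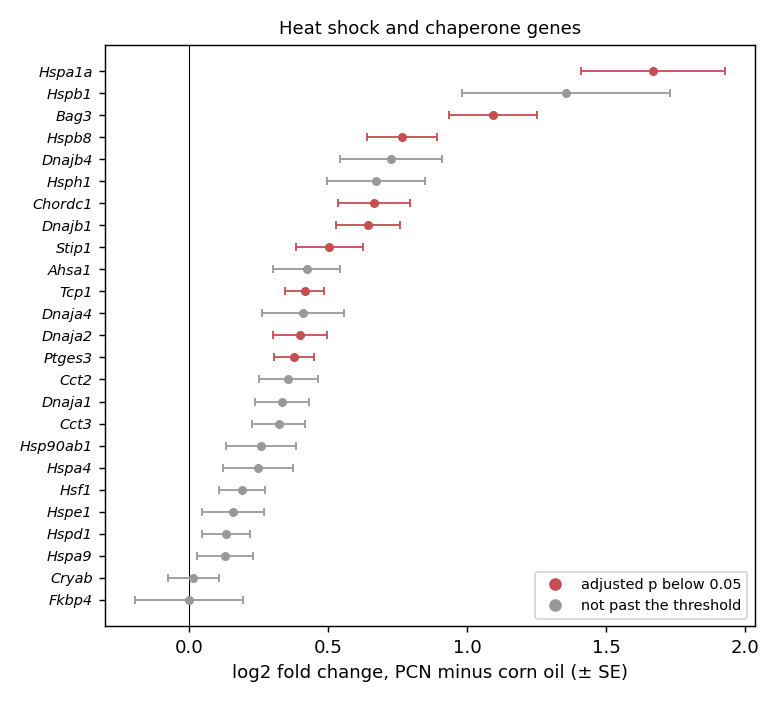
Log2 fold change (PCN minus corn oil, ± SE, 5 arrays per group on the first array type) of each heat shock and chaperone gene, red where the adjusted p was below 0.05. Of 25 genes 24 lie to the right of 0 and 9 are red.

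Other stress lists moved in the same direction with fewer calls. Endoplasmic reticulum stress genes had 3 of 32 higher (4 adjusted over the list alone) and 28 with positive values. Dnajb9 rose 1.89-fold (adjusted p = 0.00253), Ppp1r15a 1.46-fold (adjusted p = 0.0126) and P4hb 1.19-fold (adjusted p = 0.0448), the last lost under several scalings (adjusted p = 0.0596 after cyclic loess) and without single arrays (up to 0.117, without corn oil replicate 4). The set test adjusted p was 7.8e-07 and with an estimated correlation the adjusted p was 0.47. Of 33 oxidative stress genes 3 rose (8 adjusted over the list alone), namely Gsr, the sulfiredoxin Srxn1 (1.96-fold, adjusted p = 0.0354, 0.0914 without corn oil replicate 4) and Sqstm1, an autophagy receptor (1.74-fold, adjusted p = 0.00127; another probe set was called as well, and 2 others had values of -0.11 and -0.04). That list had a set test adjusted p of 0.000698, and an adjusted p of 0.47 with an estimated correlation. Among 29 acute phase genes only Il1r1, the interleukin receptor, rose (2.10-fold, adjusted p = 0.0304, 0.0781 without PCN replicate 4), with 5 adjusted over the list alone. The acute phase set test adjusted p was 0.000397, and 0.47 was the adjusted p with an estimated correlation.

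Metabolic lists gave few calls in either direction. For gluconeogenesis and glucose handling 1 of 29 genes rose and 3 fell (1 and 5 adjusted over the list alone), the set test was downward with an adjusted p of 0.00201, and the adjusted p was 0.19 with an estimated correlation. Pygl, glycogen phosphorylase, was 1.63-fold lower (adjusted p = 0.00536). Slc37a4, the glucose-6-phosphate carrier, and Ppargc1a had log2 fold changes of -0.39 and -0.58 (adjusted p = 0.0459 and 0.0285), and Gys2, glycogen synthase, rose 2.02-fold (adjusted p = 0.0451). Calls of these 3 genes were lost without corn oil replicate 4 (adjusted p = 0.121, 0.0929 and 0.112), and that of Gys2 also after cyclic loess (0.0655). Without corn oil replicate 2 of the first type and PCN replicate 5 of the second, 3 genes of the list fell and Gys2 was no longer called. Of 36 urea cycle and amino acid breakdown genes 3 fell (5 down and 1 up adjusted over the list alone), namely Cth, the histidine ammonia-lyase Hal (log2 fold change -0.65, adjusted p = 0.0356, 0.0949 without PCN replicate 1) and the cysteine dioxygenase Cdo1 (-0.55, adjusted p = 0.0148). This list was called downward with an adjusted p of 0.000167, and its adjusted p was 0.47 with an estimated correlation.

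For cholesterol synthesis 2 of 23 genes rose, also when adjusted over the list alone, and the list was not called (adjusted p = 0.434). They were Insig2, which retains the sterol sensor in the endoplasmic reticulum (2.15-fold, adjusted p = 0.0127), and Sc5d, a late enzyme of the pathway (1.95-fold, adjusted p = 0.0032). Bile acid synthesis had 1 of 20 genes lower, Akr1d1 (log2 fold change -0.30, adjusted p = 0.0426, 0.107 without corn oil replicate 4), the same count adjusted over the list alone, and a set test adjusted p of 0.142. Cyp7a1, the rate-limiting enzyme of that pathway, varied too much between animals for a call, at 11.41 ± 0.81 in corn oil and 10.61 ± 1.74 after PCN (SD, n = 5 each, adjusted p = 0.598). In fatty acid synthesis 1 of 28 genes rose, Lpin2 (1.60-fold, adjusted p = 0.0423), and 1 fell, Agpat2 (log2 fold change -0.71, adjusted p = 0.046), with 3 and 3 adjusted over the list alone. The set test adjusted p was 0.831, with a median of 0.07 and a mean of -0.01. Lpin2 was lost after cyclic loess (adjusted p = 0.0618) and another tested probe set of it had the opposite sign; without single arrays the adjusted p reached 0.124 for Lpin2 (corn oil replicate 4) and 0.0966 for Agpat2 (PCN replicate 4). Of 39 fatty acid oxidation and ketogenesis genes 2 fell, also adjusted over the list alone. These were Ppargc1a and Crot, a peroxisomal acyltransferase (log2 fold change -1.34, adjusted p = 0.0431, 0.104 without PCN replicate 4). That list had a set test adjusted p of 0.0536, one of 0.00302 without corn oil replicate 2 (0.901 when a term for 2 sets of arrays was added), and with all arrays 0.909 with an estimated correlation and 0.724 by fry.

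**Figure D5:**
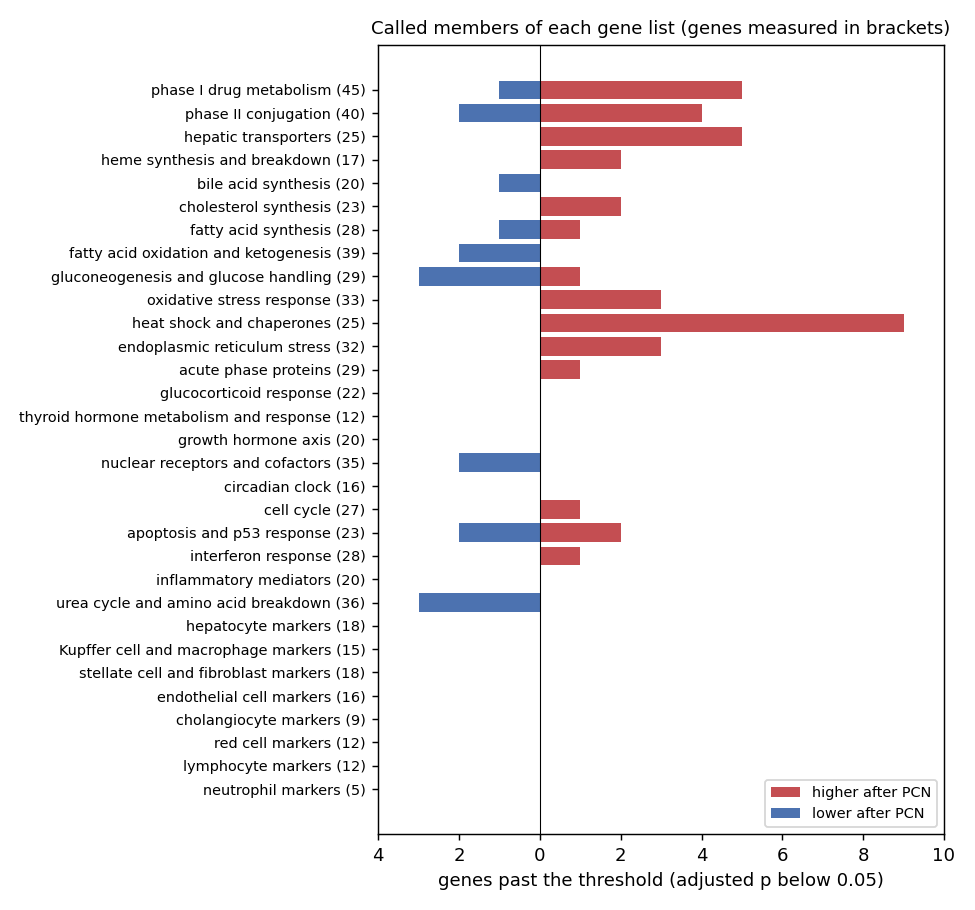
Number of genes past the adjusted p threshold in each of the 31 gene lists, with genes higher after PCN to the right and genes lower to the left of 0, and the number measured in brackets. The longest bar is that of heat shock and chaperones, 9 higher of 25, and no marker list of a cell type has a bar.

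Lists of regulators and cell state held scattered calls. Among 23 apoptosis and p53 response genes Gadd45b and Mdm2 rose while Bcl2l11 and Fas (log2 fold change -0.57, adjusted p = 0.0187, 0.0648 without corn oil replicate 4) fell, and adjusted over the list alone 3 rose and 3 fell. The set test adjusted p was 0.831, with a median of -0.05 and a mean of 0.20. Of 35 nuclear receptor genes 2 fell, Ppargc1a and Rxrg (-0.88, adjusted p = 0.0212, 0.0569 without PCN replicate 3), the same count adjusted over the list alone, with a set test adjusted p of 0.831. Ccnd1 alone rose among 27 cell cycle genes (1.99-fold, adjusted p = 0.031, 0.0877 without corn oil replicate 4; set test adjusted p = 0.296), and Oas1a alone among 28 interferon response genes (2.82-fold, adjusted p = 0.0377, 0.0973 without corn oil replicate 4; set test adjusted p = 0.348), each also the 1 gene called when adjusted over the list alone. No member was called by limma in 5 lists with 90 measured entries, where 22 had an unadjusted p below 0.05 and an unmoderated test also called 0. They were the glucocorticoid, thyroid hormone, growth hormone, circadian clock and inflammatory lists, with set test adjusted p values of 0.333, 0.831, 0.887, 0.415 and 0.971. Adjusted over the list alone, 1 thyroid hormone gene was higher and 2 were lower, 4 growth hormone axis genes were higher and 2 lower, and the other 3 lists had 0. Without corn oil replicate 2 of the first type and PCN replicate 5 of the second, limma called Igfbp2 higher (1.03, adjusted p = 0.038) and Cish lower (-1.48, 0.0308, against -0.89 and 0.451 with all arrays) in the growth hormone list. The members with the smallest p were Klf9 (log2 fold change -0.63, adjusted p = 0.113) and Nr3c1 (-0.37, 0.151) for glucocorticoids, Klf9 and Me1 (0.56, 0.12) for thyroid hormone, Igfbp2 (0.93, 0.0536) and Igf1 (-0.36, 0.0626) for growth hormone, Hlf (0.79, 0.0956) and Usp2 (0.65, 0.219) for the clock, and Cxcl1 (1.06, 0.103) and Nfkbia (0.32, 0.244) for inflammation.

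Markers of liver cell types gave no call in any of the 8 lists, over 105 measured entries by limma, of which 23 had an unadjusted p below 0.05 and 0 passed an unmoderated test. Set test adjusted p values were 0.387 for hepatocytes, 0.705 for Kupffer cells and macrophages, 0.831 for endothelial cells, 0.554 for cholangiocytes, 0.348 for red cells and 0.452 for lymphocytes. The stellate cell and fibroblast list was called upward (adjusted p = 0.0489, mean log2 fold change 0.19), with an adjusted p of 0.47 with an estimated correlation and of 0.171 without PCN replicate 2. Its array mean on the second array type was 0.15 lower after PCN (exact permutation p = 0.0714, 0.198 after adjustment over 36 array measures). On that array type the mean of hepatocyte markers was 0.32 higher (exact permutation p = 0.0159, 0.127 adjusted), and that of lymphocyte markers 0.16 lower (exact permutation p = 0.0238, 0.127 adjusted). The collagens Col3a1 and Col4a1 of the stellate cell list had log2 fold changes on the first array type of 0.43 (adjusted p = 0.0824) and 0.25 (0.148). Neutrophil markers had 5 members measured, 4 of them on the first array type, too few for the set test. Their array mean there was 0.33 higher after PCN (exact permutation p = 0.0317, 0.127 after adjustment over 36 array measures), and on the second array type it was 0.09 lower (exact permutation p = 0.175). Among them S100a9 had a log2 fold change of 0.58 (adjusted p = 0.153) and Lcn2, also an acute phase gene, one of 0.70 (adjusted p = 0.30). Adjusted over the list alone, 1 Kupffer cell gene, 1 cholangiocyte gene and 1 red cell gene were higher and 1 red cell gene was lower. Among the members nearest the threshold were Mrc1 (0.48, adjusted p = 0.053), Epb41 (0.38, 0.0504), Krt18 (0.33, 0.0687) and Ms4a1 (-0.24, 0.0805). Without corn oil replicate 2 of the first type and PCN replicate 5 of the second, 2 Kupffer cell genes, 1 stellate cell gene, 1 cholangiocyte gene and 1 red cell gene were higher and 1 lymphocyte gene was lower.

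Of the 30 lists tested 8 were called, 6 upward and 2 downward, and by camera with an estimated correlation 0 were called (lowest adjusted p 0.19; 2 had an unadjusted p below 0.05). The fry test called 3, namely heat shock, gluconeogenesis and hepatic transporters. With the term for 2 sets of arrays 6 were called, and the oxidative stress and acute phase lists were not (adjusted p = 0.113 and 0.0587). When the 10 arrays were regrouped, 28 of 100 splits, the real one included, gave at least 8 called lists, with up to 12 in a regrouping. The mixed form of fry asks whether any gene of a list changes, and not whether the list changes more than other genes. With 1964 of 11106 probe sets at an unadjusted p below 0.05, a low value from it does not set a list apart. It gave low adjusted p values for several lists that the set test did not call. They were 4.0e-06 for phase I, 8.0e-06 for phase II, 3.1e-06 for heme, 1.2e-08 for apoptosis and p53 response and 0.00025 for growth hormone. It gave 0.295 for cholesterol synthesis and 0.205 for fatty acid synthesis, and it was not run on the regroupings.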

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

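Of the tests in this part, the splits of all arrays of each type, for called probe sets and called lists, were planned. The splits for the correlation between array types, the splits without single arrays and all tests that are not splits were chosen after the results were seen. The counts of called probe sets without corn oil replicate 2 are an exception, since leaving out each animal in turn was planned. A value far from the rest of its group, by Dixon's ratio at the 95% level, was found in 20 of 238 groups of 4 or 5 arrays, where chance gives about 1 in 20. Of these 16 were among 214 groups of gene values and 4 were array measures of corn oil replicate 2.

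Corn oil replicate 2 of the first array type stood apart. Its mean correlation with the other arrays was 0.953 (0.966 to 0.979 for the rest), its 5S ribosomal RNA probe set read 8.87, and its 3′ minus 5′ differences were 2.28 for beta-actin and 2.02 for GAPDH. A mislabelled PCN animal is argued against by its response score of 0.110 over genes called without it, where 0 is the corn oil mean and 1 the PCN mean. Blood or other cell types in the sample cannot be excluded. The median deviation of this array from the other corn oil arrays was 0.34 for red cell markers, 0.28 for stellate cell, 0.21 for endothelial and 0.10 for cholangiocyte markers, each above the highest of the other corn oil arrays (0.08, 0.09, 0.10 and 0.04), while Kupffer cell, lymphocyte and neutrophil markers lay within their range. Degraded RNA is consistent with both 3′ minus 5′ differences, which exceeded the highest other array by at least 1.16, and no biological explanation was tested. Without this array 287 probe sets were higher and 106 lower, and 310 of the 361 calls were kept.

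On the second array type bright probe sets were higher after PCN. A mislabelled PCN replicate 5 is argued against by its response score of 0.648 on genes called on the other array type without that animal. The other PCN arrays scored 0.933 to 1.13. The mean of the common probe sets on PCN replicate 5, 9.41, lay within the corn oil range of 9.21 to 9.45. The other PCN arrays, to which the score is scaled, had means of 9.63 to 9.73. Whether the lower score came from a weaker response or from a less bright array was not tested. A difference in array brightness between the groups may account for the shift, since the bacterial hybridization controls, which do not come from the animals, were also higher by 0.20 (exact permutation p = 0.0476, 0.171 after adjustment over 36 array measures), against 0.02 on the first array type (exact permutation p = 0.873). A change in the RNA of the animals cannot be told apart from it, because the shift of the common probe sets exceeded that of the same animals on the first array type by 0.17 with an exact permutation p of 0.175. After cyclic loess the brightest of 10 groups had a median of 0.03, and 363 of 577 calls were kept.

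Heat shock and chaperone genes were higher after PCN. A brightness difference as the whole cause is argued against by the mean log2 fold change of 0.46 after cyclic loess, and the array of corn oil replicate 2 by a mean of 0.45 without it, against 0.49 with all arrays and 0.41 with a term for the 2 sets of arrays described below, where 5 of the genes were called. Stress or handling at killing cannot be told apart from a response to PCN: the immediate early genes had a median of 0.055 against 0.40 for the heat shock list, but the 19 measured went both ways, with an SD of 0.43, Jun called higher and Ier2 lower. The bootstrap interval of the median was -0.068 to 0.16 for the immediate early genes and 0.26 to 0.64 for the heat shock list. These intervals resample genes and not animals, so they do not settle the question. A response to PCN is a hypothesis, found and tested on the same data. The vehicle group had the same injection and fast, and its livers were also taken at 8 h. Killing or handling could make the difference only if it differed between the groups, which was not tested. Chance is not excluded for the number of called lists, since 28 of 100 splits, the real one included, gave at least 8, with up to 12 in a split other than the real one.

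Few splits gave as many probe sets past the threshold as the real one. On neither array type does this exclude another structure of the arrays as a source of calls. On the second, how the arrays read went with the treatment. Every PCN array there had a lower median than every corn oil array, with group means of 6.27 and 6.32. The exact permutation p was 0.0159, and 0.127 after adjustment over 36 array measures. The splits cannot tell that difference from PCN. On the first, the splits of all arrays hold corn oil replicate 2, which stood apart. With all arrays, on the first array type only 1 of 100 splits, the real one, gave as many as 361, and the highest other gave 5. On the second array type only 1 of 100, the real one, gave as many as 577, and the highest other gave 2, and without PCN replicate 5 only 1 of 35, the real one, gave as many as 1477, and the highest other gave 1. On the first array type without corn oil replicate 2, 2 of 100 splits gave at least the 393 of the real one, and the other gave 973, of which 52 were also called for the treatment. That split set corn oil replicate 1 and PCN replicates 1, 3, 4 and 5 against the rest. Its 2 sets did not overlap in 7 of 10 array measures, the bacterial hybridization controls among them (9.08 to 9.33 against 8.76 to 9.01), where any other of 126 splits reached at most 3. The split was picked by its calls on these same arrays, and some measures overlap in what they read, so the 7 are not independent. A split by the same animals called 0 probe sets on the second array type by limma (489 at an unadjusted p below 0.05, 0 by an unmoderated test). The sets differ in how the arrays read, the labels name no batch, and 4 of 5 PCN arrays lie in the brighter set, so part of the calls on the first array type may come from it. With a term for the sets 149 were higher and 161 lower, and 179 of the 361 calls were kept. All 361 kept their sign, and some lost calls kept a log2 fold change of about the same size. A lost call alone therefore does not show that the sets made it. For the correlation between the array types only 1 of 100 splits of the 9 shared animals, the real one, gave as large a value, but the highest other gave 0.619 against 0.620, so the correlation says little about PCN.

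Single arrays stood apart from their group for these genes, given as log2 values. In corn oil, Ces2c read 8.81 in replicate 3, Gsr 7.33 in replicate 2, Fmo1 10.97 in replicate 1, Ppargc1a 7.28 in replicate 1 of the second array type, Gys2 11.04 in replicate 5, Igfbp2 10.43 in replicate 1, Nr1i2 10.18 in replicate 2 and Cyp7a1 10.0003 in replicate 3. After PCN, Por read 12.35 in replicate 5, Abcb1a 9.89, Agpat2 9.37 and Usp2 9.74 in replicate 2, Oas1a 11.39 and Krt18 12.23 in replicate 1, and Lcn2 9.93 and Cyp3a23-3a1 13.72 in replicate 4.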

How the results depend on the processing

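Trimmed mean scaling joined to a pseudocount of 16 was the transformation first planned for the main result. Either step alone, cyclic loess, the common probe sets and a term for 2 sets of arrays were chosen after seeing the data. So was the use of the values as deposited. The cause of each change below was not tested unless stated. Of 107 values of named genes 77 were called, of which 30 stayed called under every alternative and 47 lost the call under at least 1; of 30 not called, 16 were called under at least 1, and 0 reversed. The main counts of higher and lower probe sets were 256 and 105 on the first array type and 402 and 175 on the second, with a drug metabolism share of 3.40%, 8 called lists and a correlation between array types of 0.623. The correlation was 0.588 with no filter and 0.658 with the filter at the 50th percentile. Lower probe sets numbered 72 on the second array type with a common median and 181 on the first after quantile normalization. With trimmed mean scaling and a pseudocount of 16 they were 175 and 501 on the 2 types, with the scaling alone 176 and 496, and after cyclic loess 168 and 100. Array weights gave 768 and 283, then 868 and 607, with a share of 1.85%. The unmoderated test gave 77 and 27, then 25 and 21, with a share of 8.65%, and 45 of 107 named values lost the call. Fewer calls follow from variances that are not pooled. Replicate number as a block left 62 lower on the first type, 163 and 40 on the second, and a share of 6.21%, but same-number animals of the 2 groups were not alike (correlations of their deviations -0.30 to 0.28), so the numbers do not pair them. Centring on the common probe sets gave 240 and 5358 on the second type and a share of 1.05%, since it lowers all PCN values there by the shift of those probe sets. A term for 2 sets of arrays on the first type without corn oil replicate 2 gave 149 and 161 and a correlation of 0.545, and 21 of 86 named values lost the call. The sets partly coincide with the treatment, but leaving out corn oil replicate 2 alone lost 5 of 86, so the causes were not separated. The list count was 0 with an estimated correlation and 3 by fry. Leaving out each animal in turn gave 107 to 343 higher and 43 to 106 lower on the first type, 69 to 905 and 15 to 572 on the second, correlations of 0.595 to 0.633, shares of 1.89% to 8.92% and 6 to 10 called lists; for PCN replicate 5 of the second type, the count rose to 905 and 572. Signal over background could not be judged from log2 values alone, and dim probe sets were removed by the filter.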

Other observations

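The tests in this part, and the genes singled out in its first paragraph, were chosen after the values were seen.

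Among the 31 genes called on both array types were further genes of membrane traffic and cell structure. Tmed9, a cargo receptor of the early secretory pathway, had log2 fold changes of 0.65 and 1.04 on the first and second array types, Arcn1, a coat protein subunit, 0.37 and 0.56, Mia3, an export factor of the endoplasmic reticulum, 0.48 and 0.69, and Atl2, which shapes that organelle, 0.63 and 0.89. Mal2, a protein of apical transport, had 1.32 and 0.92, and Fermt2, an integrin activator, 0.56 and 0.93. The retinol dehydrogenase Rdh10 had 1.03 and 1.38, while Cyp26a1, which removes retinoic acid, rose on the first array type. No list of secretory or retinoid genes was fixed beforehand, so no theme was tested.

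Mdm2 rose on both array types, and a hypothesis was that p53 activation raised it. The other p53 target genes argue against this for the set: the median log2 fold change of 23 measured was -0.14 (95% bootstrap interval -0.29 to 0.03, SD of the members 0.33) against 2.29 for Mdm2, 0 were called higher by limma (3 at an unadjusted p below 0.05, 0 by an unmoderated test) and 1, Fas, was called lower (7 at an unadjusted p below 0.05). The bootstrap interval resamples genes and not animals, so it does not measure the spread between animals. Another source of the Mdm2 change was not tested.

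The arrays of an animal could be matched across array types. Over the 100 common probe sets, all 9 arrays of the second type correlated best with the array of the first type that bears the same group and number (0.35 to 0.81 across probe sets, which are not independent replicates).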
